A study of Taeniopygia guttata with 36 samples.

How the data were processed

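Brain tissue came from male zebra finches, songbirds that learn their song by ear. HVC and RA are forebrain nuclei of the pathway that drives song. Per the labels' protocols, early-deafened birds lost both cochleae 17 to 23 days after hatching, and were kept with their family until day 32 to 41. Every bird then spent at least 2 days alone in a sound-attenuated box and was sampled in silence and darkness. Tissue was laser-microdissected, and total RNA was amplified with a whole transcriptome kit. Per the labels' protocols, RNA integrity was read in 4 randomly chosen samples only and lay between 5.9 and 7.1, with 1.69 to 2.35 ng/μl of RNA. A mass of 1.7 µg of amplified cDNA was labelled with Cy3, and each sample was hybridized to 1 array of a custom Agilent zebra finch design. The design placed intact and early-deafened samples of 1 area and age on the same slide.

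The deposited scanner files hold spot intensity on a linear scale from 1 channel, read with Agilent Feature Extraction 9.1.1.1 per the file headers. The processed signal was background-subtracted and spatially and multiplicatively detrended, with surrogate values near background, per the file headers, and was not normalized between arrays. The deposited series table holds log2 values whose normalization is not given in the sources used here. Its columns had the same median within an area, 11.02 in HVC and 10.97 in RA. Set against the log2 processed signal of their own arrays, the 18 HVC columns correlated at 0.998 to 1.000. The 18 RA columns correlated with their own arrays only at -0.0130 to 0.0036, while they correlated with each other at 0.918 to 0.984. The order of the RA values in that table could not be matched to the probes, so the table was used for HVC only, as an alternative.

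From the processed signal, the log2 value minus the array's 75th percentile was computed, with control spots and spots marked as outliers left out. Levels below are on this scale. Spots of 1 probe sequence were averaged, from 43552 spots to 41606 sequences. A probe was tested where it was well above background on all arrays of at least 1 group and had at least 2 values left in every group of 3. Each area was fitted with limma 3.58.1 in R 4.3.3, with a mean for each of 6 groups and a shared spread, followed by moderated tests and Benjamini-Hochberg adjustment at 0.05. RA minus HVC used all 36 arrays and 12 group means. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, beside camera with an estimated correlation and fry. Their p-values were adjusted over the lists of the same comparison only. On simulated data without slide structure, with 50 probes changed at each size, the HVC test of deafening recovered 52% of changes of 1 log2 unit and 98% of changes of 2. For RA these were 44% and 88%. For old birds alone the test recovered 54% of changes of 2 log2 units in HVC and 56% in RA. RA minus HVC recovered 82% of changes of 1 log2 unit. False calls made up 8.2% of calls for deafening in HVC and 7.6% in RA. In old birds alone they made up 9.6% and 10.2%, and for RA minus HVC 5.9%, all above the threshold of 0.05.

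Most probes carry clone names that are not paired with genes, and are given by their identifiers. Among 287 custom probe names, 7 matched the RefSeq gene table of assembly bTaeGut7.mat by accession and 58 by symbol. A further 19 were read from descriptive labels, 55 kept the symbol of the array's design and 148 stayed unnamed. The result was 147 named sequences for 136 genes, out of 23294 genes in the table, which was used for names only. Symbols in mixed case, such as Cd53 or the Olfr names, are the design's own, and which zebra finch gene they measure was not checked. A gene was represented by its brightest probe. Of 31 gene lists fixed in advance, 13 had a named member and 2 had at least 4, axon guidance and monoamine and acetylcholine receptors. Only those 2 were tested as lists.

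The groups, main tests, gene lists and most alternatives were fixed before the data were examined. The rule for named genes was fixed then too: up to 10 called genes with the largest rise and 10 with the largest fall, up to 4 called members of each list, or the 5 genes with the smallest p where fewer than 5 were called. The old minus juvenile comparison, the scan day block, the fit without slide 1, the detection covariate, the fits of single slides, the size of called changes under a slide block, the adjustment over named genes alone and the minimum of 4 list members were chosen after seeing the data. Alternatives covered background correction, normalization, the filter on dim probes, the series table, slide and scan day, array weights, the threshold, pairing, the samples in the fit and each array left out. Each fit of a single slide of 1 area held 4 arrays and terms for age and auditory state. Its spread therefore rests on very few values, and its counts are uncertain.

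The 75th percentile of the processed signal was 3520 to 11502 across arrays, and 93.4% to 98.9% of probes were well above background. The number of arrays limits the precision. The labels state 24 birds for 36 samples, so some birds gave both areas, and samples are not tied to birds. Tests between areas treat all arrays as independent, which leaves out any correlation between the 2 areas of 1 bird. Within 1 area the samples were taken as separate birds. A gene was given a fold bound where 1 group lay below background on all its arrays. The bound sets the brighter mean against the mean of, per array, the higher of the lowest signal well above background and the probe's own signal.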

Results

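Gene expression was measured in HVC and RA of male zebra finches that were intact or had been deafened before fledging. Juveniles were sampled at 53 to 57 days after hatching, young birds at 121 to 135 days and old birds at 504 to 787 days. Each of the 12 combinations of area, auditory state and age had 3 arrays, on 9 slides read on 4 scan days. A median of 97.2% of probes was well above background. The lowest values, 93.4% to 94.8%, were those of slide 1, which held RA of juvenile and young birds.

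Arrays grouped mainly by area and slide. The first component held 17.6% of the variance and the second 13.7%. Group means accounted for 31.5% of the variance in HVC and slides for a further 35.3%. In RA these shares were 26.3% and 42.6%. Age accounted for 20.4% in HVC and 13.1% in RA, and auditory state, after age, for 3.39% and 4.84%. Means fitted to 18 arrays take up part of the variance even when arrays are grouped at random. That part was not computed, so these shares alone do not show an effect of group, slide, age or auditory state. A probe for GFP, a protein that finches lack, was well above background on 1 of 36 arrays.

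**Figure D1:**
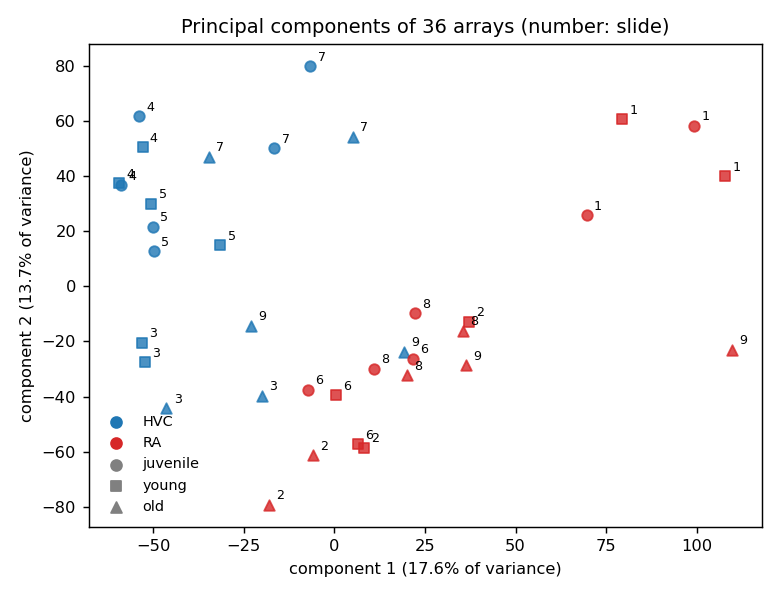
Principal components of the 36 arrays, with component 1 (17.6% of variance) and component 2 (13.7%) on the axes in arbitrary units; colour marks the area, symbol shape the age class and the number the slide. RA arrays of slide 1 stand apart from the other RA arrays.

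RA and HVC were compared to ask which genes distinguish these song nuclei. A clone labelled as putative ER81, an ETS transcription factor, showed the clearest rise in RA among the probes that represent named genes. It stood at 0.44 ± 0.28 against -1.51 ± 0.44 in HVC (SD, n = 18 each). Its log2 change of 1.95 ± 0.12 (SE) had an adjusted p of 2.36e-12, and all 18 RA arrays lay above the HVC mean. ETV1, the current name of ER81, has its own probe, which was 0.71 higher (adjusted p = 0.0248). The ETV1 probe was the brighter, in RA of young birds at 0.99 (deafened) and 1.12 (intact) against 0.21 and 0.28. The 2 names were counted as separate genes. If both measure ETV1, the brightest-probe rule would give the gene the smaller change. FNDC9, a fibronectin type III domain protein, went the other way and was 7.84-fold lower in RA, a log2 change of -2.97 ± 0.32 (adjusted p = 4.21e-08).

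Of 6 measured axon guidance genes, 5 stood lower in RA and 1 higher. ROBO2, a receptor for SLIT proteins, was lower in RA by a log2 change of -0.97 (adjusted p = 1.92e-05), and the ephrin ligand EFNB2 by -0.54 (adjusted p = 0.000312). SLIT3, which encodes a secreted SLIT ligand, was 0.59 higher in RA (adjusted p = 0.0215). Of the 6, 3 passed over all probes, 4 passed adjusted over the list alone, and the list as a whole did not differ from other genes (adjusted p = 0.343, camera). In fry, which tests for movement in 1 direction on balance, its adjusted p was 0.00672, downward. Dopamine receptors also differed in direction. The D1D-like receptor was lower in RA (-0.75, adjusted p = 5.96e-05), as was the D1a receptor (-0.59, adjusted p = 0.00173), while the D3 receptor was higher (0.54, adjusted p = 0.0307). The monoamine and acetylcholine receptor list does not hold the D1D-like receptor. Of its 4 measured members, D1a and D3 passed, and the list did not (adjusted p = 0.856).

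EGR1, a transcription factor induced by neuronal activity and known in songbirds as ZENK, was lower in RA by -0.74 (adjusted p = 9.33e-05). KCNA4, an A-type potassium channel, changed by -1.37 (adjusted p = 0.000158) and was above background on 16 of 18 RA arrays. Jph4, a junctophilin, changed by -1.06, and GPM6A, a neuronal membrane glycoprotein, by -0.65. Abca6, a lipid transporter family member, changed by -0.59. BARD1, a partner of BRCA1, changed by -0.72 but was above background on 8 RA and 11 HVC arrays. The remaining genes higher in RA were ELK3, an ETS factor (0.73), FUT8, a fucosyltransferase (0.49), and NKX2-2, a factor of the oligodendrocyte lineage (0.37).

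In limma's test 7760 of 40486 probes differed between the areas, 3557 higher and 4203 lower in RA, and 1350 by at least 2-fold. Which direction was more frequent depended on scaling, with 4094 higher and 4027 lower after quantile normalization and 4025 and 3822 after median centring. Among 122 named genes, 23 passed, 7 higher and 16 lower in RA, with putative ER81 and ETV1 counted apart. Unnamed probe 0205P0018B12 changed by 4.05 and 0203P0002P22 by -5.25. With a random block for 8 birds 9535 passed, with the 18 genes named here among them. These 8 were taken as shared where 1 sample of each area matched in auditory state and age in days, while 24 birds for 36 samples imply 12 shared birds, so the block is incomplete. Each slide but slide 9 held 1 area. With slide as a fixed block, under which areas meet only on slide 9 (4 arrays of old birds), 253 probes passed, among the 18 genes named here ER81 and FNDC9, and a fit of that slide alone called 3. The called changes kept a median of 98.2% of their size under this block and 92.0% their direction, though slide 9 had helped to pick them. Their SE grew by a median of 2.88 times, so that calls were lost mainly to precision. Sizes held for ROBO2 (-1.08), EGR1 (-0.84), the D1a receptor (-0.82) and GPM6A (-0.70), but not for KCNA4 (-0.54 ± 0.59), EFNB2 (-0.06 ± 0.32), SLIT3 (0.10 ± 0.55) and FUT8 (0.13 ± 0.29; SE). With slide as a random block 3800 passed, and ETV1, SLIT3, the D3 receptor, NKX2-2, GPM6A, Abca6 and BARD1 did not. With 1 array left out, the D3 receptor lost its call in 9 of 36 fits and BARD1 in 5, and the other 16 genes in none. Within 1 of the 6 bird groups each, the D1D-like receptor, Abca6, ETV1, the D3 receptor, NKX2-2 and SLIT3 went the other way. On slide 9, 19 of the 23 named genes kept their direction, with KCNA4 at -0.28 and EFNB2 at -0.17.

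**Figure D2:**
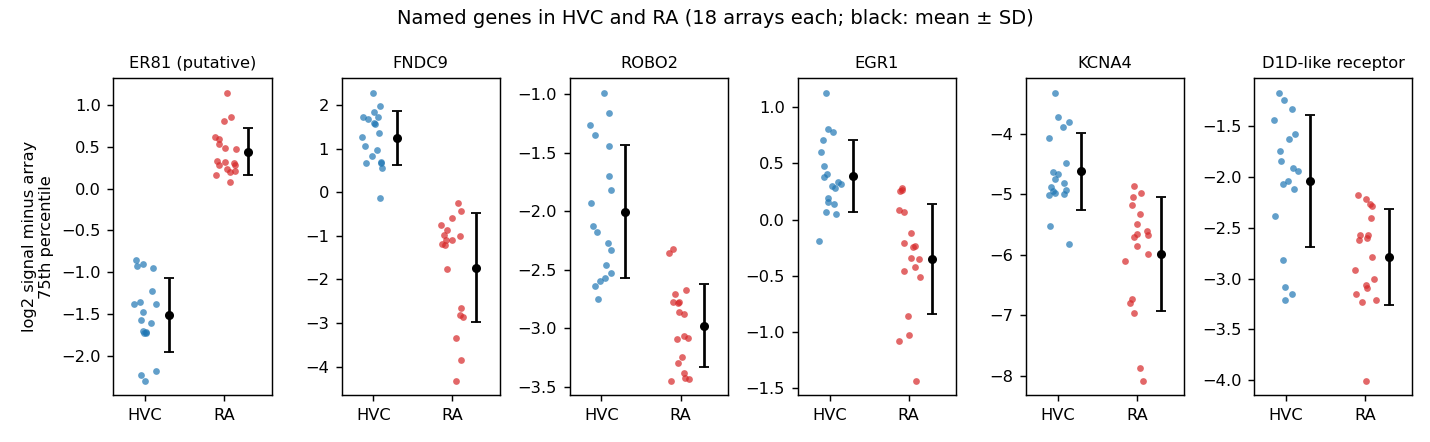
Level of 6 named genes in HVC (blue) and RA (red), as log2 signal minus the array's 75th percentile; points are the 18 arrays of each area and black marks the mean ± SD. Putative ER81 is higher in RA and FNDC9, ROBO2, EGR1, KCNA4 and the D1D-like receptor are lower.

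The comparison of deafened with intact birds asks what hearing contributes to expression in each nucleus. In HVC, averaged over the 3 ages, Olfr978 stood at -6.35 ± 0.38 in deafened and -5.51 ± 0.55 in intact birds (SD, n = 9 each), with all 9 deafened arrays below the intact mean. Its log2 difference was -0.84 ± 0.19 (SE), and it was the 1 of 121 named genes to pass an adjustment over named genes alone. It did not pass over all probes (adjusted p = 1). Cd53, a tetraspanin of immune cells, differed by -0.50, BARD1 by -0.56 (above background on 5 deafened and 6 intact arrays), Jph4 by -0.67 and DNAJC18, a J-domain chaperone, by -0.29, and none passed. Axon guidance genes did not move as a list in HVC (adjusted p = 0.751), nor did the receptors (adjusted p = 0.542). None of 40368 probes passed in limma's test, and 563 had an unadjusted p under 0.05 against 2018 expected by chance for independent arrays. Intact and deafened arrays shared slides, arrays of 1 slide resembled each other, and this test held no slide term. Its p-values can therefore be too large, and the low count is not a measure of the effect. With pairs of 1 age and slide as a block 0 passed, and in fits of single slides 8 passed on slide 4 and 0 on slides 3, 5 and 7. Across probes, the deafening differences of slides 3, 4, 5 and 7 correlated with those of the other slides at 0.056, 0.0013, -0.013 and -0.251. The calls on slide 4 thus came without a like pattern on the other slides.

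In RA, averaged over the 3 ages, axon guidance genes were higher in deafened birds as a list (adjusted p = 8.85e-05, camera; adjusted p = 0.0215 with an estimated correlation; adjusted p = 0.0246, fry). Each adjustment covered only the 2 lists of this comparison, although the lists were tested in other comparisons too. The unadjusted p was 0.0108 in camera with an estimated correlation and 0.0123 in fry. An adjustment over all list tests, which was not made, could raise these above 0.05. Log2 differences of all 6 members were above 0. SLIT3 differed by 0.54 ± 0.23 (SE), its receptors ROBO2 by 0.42 ± 0.16 and ROBO1 by 0.31 ± 0.25, the repulsive cue SEMA3A by 0.25 ± 0.37, and the ephrins EFNA5 and EFNB2 by 0.24 ± 0.16 and 0.18 ± 0.15. In juveniles, however, 4 of the 6 stood lower in deafened birds, SEMA3A at -0.37, EFNA5 at -0.13, SLIT3 at -0.12 and ROBO1 at -0.041, while in young and in old birds all 6 differences were above 0. No member passed alone, either over all probes or adjusted over the list alone. The camera test used 5 of the 6, those with a value on every array. Within slides the mean of the 6 differences was 0.33 on slide 1, 0.54 on slide 2, -0.05 on slide 6, 0.02 on slide 8 and 1.29 on slide 9, which held 2 RA arrays, so the list was not higher on slides 6 and 8. The receptor list did not move (adjusted p = 0.730).

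Among single genes in RA, FXYD2, a regulatory subunit of the sodium pump, differed by 0.56 and the oestrogen receptor ESR1 by 0.45. The melatonin receptor MTNR1A differed by 0.46, and all 9 deafened arrays lay above the intact mean for both receptors. These genes did not pass (adjusted p = 1 each), and 0 of 40329 probes passed in limma's test, with 1170 at an unadjusted p under 0.05 against 2016 expected. As in HVC, that expected count assumes independent arrays. The age and slide pair block also gave 0, slide as a random block gave 1, and single slides gave 59 on slide 2 and 0 on slides 1, 6 and 8. Across probes, the deafening differences of slides 1, 2, 6 and 8 correlated with those of the other slides at 0.252, 0.037, 0.173 and -0.076. The calls on slide 2 thus came with little likeness to the other slides.

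**Figure D3:**
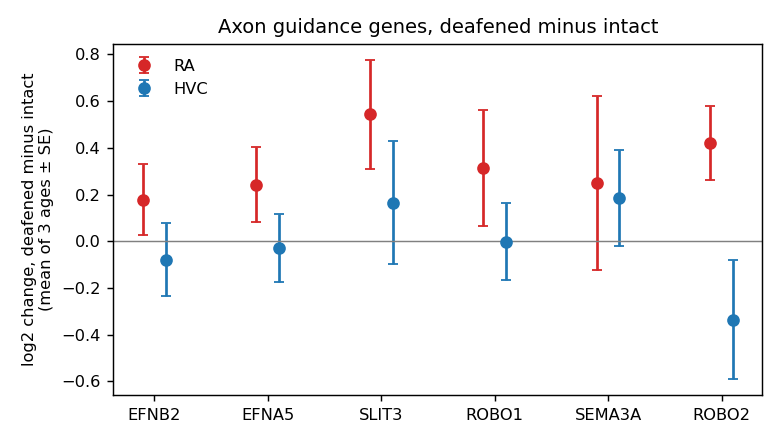
Log2 difference between deafened and intact birds for 6 axon guidance genes in RA (red) and HVC (blue), as the mean of 3 ages ± SE. All RA values lie above 0, from 0.18 to 0.54, and HVC values lie on both sides of 0.

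At single ages, groups of 3 were compared. In HVC of juveniles CHRNA1, a nicotinic receptor subunit, was not well above background on any deafened array and at least 2.47-fold brighter in intact birds. UMPS, an enzyme of pyrimidine synthesis, was 0.89 higher in deafened juveniles, and Olfr978, BARD1 and Cd53 differed by -0.81, -0.81 and -0.53, with BARD1 above background on 1 deafened and 2 intact arrays. In young birds the leading genes were Olfr978 (-1.20), Aard (-0.998), UMPS (-0.89), BARD1 (-0.84) and PLAG1 (-0.67). Old birds showed Cd53 at -1.02, Jph4 at -1.17, oasl at -0.52, the D1D-like receptor at -0.50 and ROBO2 at -0.84. No gene passed (adjusted p = 1 each). Limma called 0 probes at each age, with 475, 563 and 1153 at an unadjusted p under 0.05 in juvenile, young and old birds. Slide as a random block called 1 in young birds, and array weights called 1 in young and 5372 in old birds.

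In RA, FXYD2 was 0.96 higher in deafened juveniles and 1.77 higher in deafened young birds, and differed by -1.06 in old birds. It was the 1 named gene to pass an adjustment over the 115 named genes alone in young birds, and the 1 to pass it in the test of whether the deafening difference changes with age. SLIT3 differed by 1.53 in old birds, from -1.27 ± 0.60 against -2.80 ± 0.67 (SD, n = 3 each). ESR1 differed there by 0.75, Wbp5 by -0.91, and Mterf was not above background on deafened arrays and at least 1.73-fold brighter in intact birds. Juveniles showed Olfr711 at 1.90 (above background on 3 deafened arrays and 1 intact), Olfr284 at -1.07 (2 and 3 arrays), the nuclear receptor RORB at -0.68 and FNDC9 at -1.43. Young birds showed ESR1 at 0.68, KCNA4 at 1.18 (3 and 2 arrays), ROBO2 at 0.47 and MTNR1A at 0.54, though MTNR1A stood at -0.033 with array weights. No gene passed over all probes (adjusted p = 1 each), and limma called 0 probes at each age, with 447, 1001 and 1178 at an unadjusted p under 0.05. In old birds a fixed slide block called 4 probes and a fit of the 2 groups alone called 2, and in young birds array weights called 19.

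The interaction of auditory state with age asks whether age changes differ without hearing. In HVC, UMPS led with deafening differences of 0.89, -0.89 and 0.06 in juvenile, young and old birds, followed by CHRNA1, which was not above background in deafened juveniles, Cd53 (-0.53, 0.05 and -1.02), Aard and PLAG1. In RA, FXYD2 led, followed by SLIT3 (-0.12, 0.22 and 1.53), Mterf, Wbp5 and Olfr711. Limma called 0 probes in either area, with 626 in HVC and 603 in RA at an unadjusted p under 0.05. Array weights called 10 in HVC.

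From the juvenile to the young age, over which finches complete song learning, the D1D-like receptor in HVC went from -1.43 ± 0.25 to -1.90 ± 0.18 (SD, n = 6 each), a change of -0.46 that did not pass (adjusted p = 0.802). Cd53 changed by 0.43, PNRC2, a nuclear receptor coactivator, by 0.57, the protocadherin Pcdha2 by -0.56 and Olfr139 by 0.61, without passing. In RA the mitotic kinesin KIF20A changed by -0.62, FUT8 by -0.48, EGR1 by -0.49, EDA2R by -0.73 and Olfr711 by 0.78 (adjusted p = 1 each), the last above background on 6 young and 4 juvenile arrays. Neither list moved in HVC (adjusted p = 0.433 for both) or in RA (adjusted p = 0.181 for axon guidance and 0.230 for receptors). Limma called 0 probes in HVC, with 2480 at an unadjusted p under 0.05, and 0 in RA, with 697. With slide as a fixed block both counts were 0, and on single slides 6 passed on HVC slide 4 and 0 on HVC slide 5 and on RA slides 1 and 6.

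With hearing, the leading HVC genes of this change were the D1D-like receptor (-0.69), CHRNA1 (-1.41) and PAQR5, a membrane progestin receptor (0.86), and without hearing UMPS (-1.19), Cd53 (0.72) and FUT8 (-0.38). In RA they were KIF20A (-0.85), Olfr711 (1.70) and EGR1 (-0.78) with hearing, and putative ER81 (-0.41), FUT8 (-0.50) and KIF20A (-0.39) without. Olfr711 was not above background on most intact juvenile arrays, so the size of its change is uncertain. No probe passed in limma's tests, with 1102 and 1382 at an unadjusted p under 0.05 in HVC and 611 and 480 in RA. Across 40368 HVC probes, the changes with and without hearing correlated at r = 0.326 (Spearman's rho = 0.404), where 178 of 200 regroupings of the same arrays within each age gave a value at or below it, the real one included (median of the others 0.166). Across 40329 RA probes r was 0.133 (rho = 0.186), and 195 of 200 regroupings were at or below it (median -0.119). Probes are not independent replicates, and both changes share slides. Without deafened young array 1 the HVC value was 0.145, and without deafened juvenile array 1 the RA value was 0.018.

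Between young and old birds, PAQR5 in HVC went from -4.52 ± 0.43 to -6.08 ± 0.60 (SD, n = 6 each), a log2 change of -1.56 (adjusted p = 0.0827) with all 6 old arrays below the young mean. The D1D-like receptor changed by -0.89 (adjusted p = 0.135), MCPH1, the microcephalin gene, by -1.18, Olfr131 by -0.86 and the dicarboxylate transporter SLC13A3 by -0.63. None passed over all probes, though PAQR5 did so without either of 2 arrays and with all 36 arrays in 1 fit, and 3 of 121 passed an adjustment over named genes alone. In RA the growth factor FGF1 changed by 1.49 (adjusted p = 0.619), PAQR5 by -0.70, Hist2h2be by 0.87, UMPS by 1.17 and cytochrome c, CYCS, by -0.68. Neither list moved in HVC (adjusted p = 0.944 for axon guidance and 0.178 for receptors) or RA (adjusted p = 0.515 for both).

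Called probes of this comparison were unnamed. In HVC 8 passed, 6 higher and 2 lower in old birds, and in RA 4 passed, all higher. Quantile normalization called 6 in HVC, all higher, and 4 higher and 2 lower in RA, and normexp correction called 3 higher and 2 lower in RA. Probe 0062P0001C06 rose in both areas, by 4.87 in HVC (adjusted p = 0.00824) and 4.28 in RA (adjusted p = 0.0441), in 6 of 6 old arrays each. Probe 0058P0043A03 rose by 6.21 in HVC, and 0105P0027C06 changed by -1.89. With slide as a fixed block 4 passed in HVC and 1 in RA, array weights gave 8401 in HVC, and in fits of single slides 1 passed on HVC slide 3 and 36 on RA slide 2. Without deafened old array 1 of HVC 92 passed, without the slide 1 arrays 0 passed in RA, and scan day as a block left 5 in HVC and 0 in RA.

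Old and juvenile birds, the widest age span, were compared after the data had been seen. In HVC all 5 named genes that passed fell with age. The D1D-like receptor fell by 1.36 on the log2 scale, from -1.43 ± 0.25 to -2.79 ± 0.46 (SD, n = 6 each; adjusted p = 0.00318). FUT8 fell by 0.70 (adjusted p = 0.0227), PAQR5 fell by 1.17 (adjusted p = 0.0333), and NKX2-2 fell by 0.72 (adjusted p = 0.0454). Olfr131 fell by 0.91 (adjusted p = 0.0458) and was above background on 4 of 6 old arrays. For each of the 5, all 6 old arrays lay below the juvenile mean. With 1 array left out, the D1D-like receptor lost its call in 0 of 18 fits, FUT8 in 3, PAQR5 in 6, Olfr131 in 13 and NKX2-2 in 14. The D1a receptor changed by -0.64 without passing (adjusted p = 0.0700), and the receptor list did not pass either (adjusted p = 0.131, camera; 0.0522, fry), nor did axon guidance (adjusted p = 0.589).

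In RA none of the 115 named genes passed. PAQR5 changed there by -1.06 (adjusted p = 0.215), FUT8 by -0.67, ROBO1 by -0.90, KIF20A by -0.49 and FGF1 by 1.13. Neither list moved in RA (adjusted p = 0.841 for both). Unnamed probe 0062P0002D06 rose by 5.93 in HVC, where it was above background on 2 of 6 juvenile arrays, and 0104P0020D05 fell by 3.61. In RA 0202P0006A17 rose by 4.25, with 1 of 6 juvenile arrays above background, and 0203P0051K03 fell by 2.90. The sizes of the 2 rises are uncertain for that reason.

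In HVC 1280 probes passed, 675 higher and 605 lower in old birds, and 723 differed by at least 2-fold. Other scalings gave slightly more lower than higher, 758 against 749 with normexp correction, 767 against 741 with quantile normalization and 741 against 684 with median centring. In RA 32 passed, 9 higher and 23 lower. With slide as a fixed block 20 passed in HVC and 2 in RA, with slide as a random block 633 in HVC, and with scan day as a block 100 and 18. Array weights gave 11782 in HVC and 51 in RA, and in RA 92 passed with all 36 arrays in 1 fit and 7 with only the groups compared. Under the fixed block the D1D-like receptor stood at -1.32, FUT8 at -0.83, PAQR5 at -1.14, NKX2-2 at -0.60 and Olfr131 at -0.93, and none passed. HVC slide 7 and RA slide 8 held both ages; fitted alone each called 0, and on slide 7 the same 5 genes changed by -1.27, -0.86, -1.53, -0.70 and -1.06. The HVC count was 289 without deafened juvenile array 2 and 2917 without deafened old array 1, and the RA count was 1 without the arrays of slide 1.

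**Figure D4:**
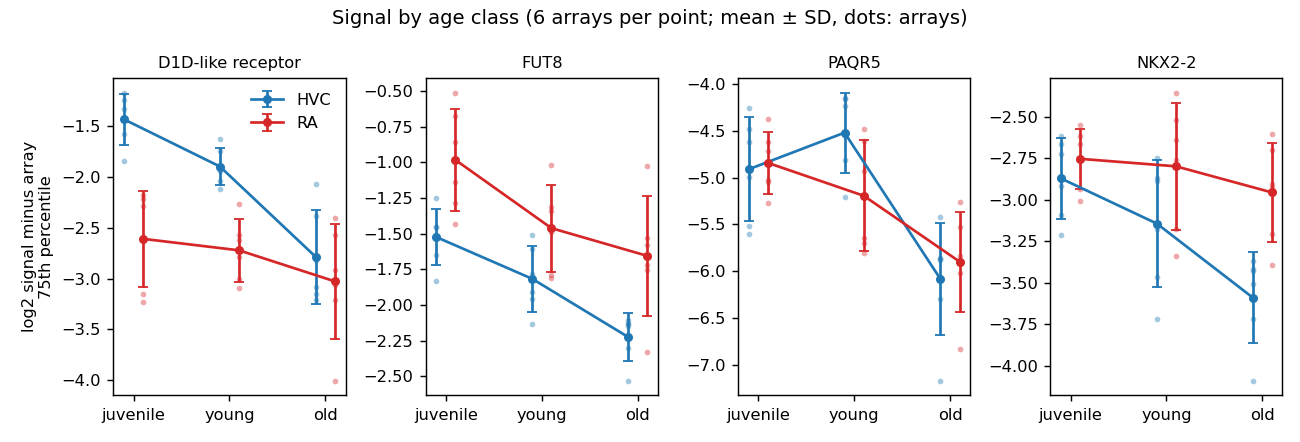
Level of 4 named genes by age class in HVC (blue) and RA (red), as log2 signal minus the array's 75th percentile; small points are arrays and large points with bars the mean ± SD of 6 arrays. All 4 are lower in old than in juvenile HVC, the D1D-like receptor with a log2 change of -1.36.

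**Figure D5:**
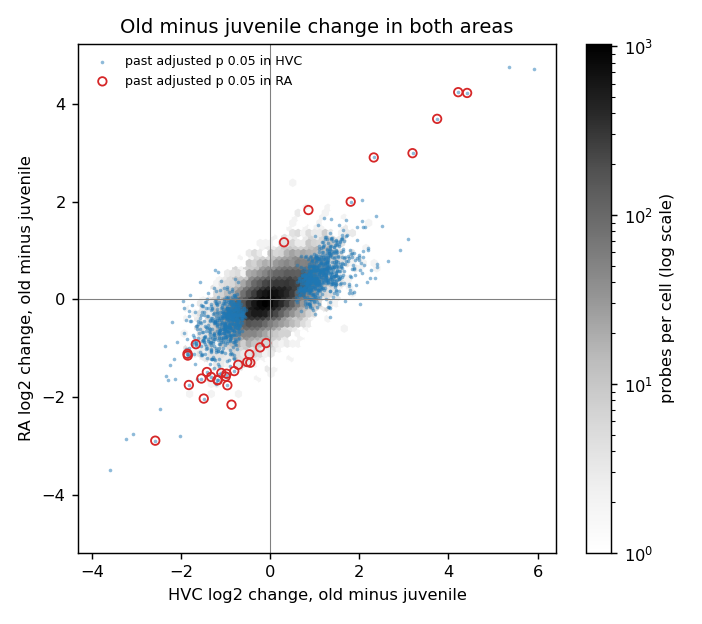
Log2 change from juvenile to old birds in HVC (horizontal) and RA (vertical); grey cells count all tested probes on a log scale, blue points passed in HVC and red circles passed in RA. Of the 1267 probes that passed in HVC and were tested in both, 95.3% had the same sign in RA, counted on all arrays with the slide that holds both areas included.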

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

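The old minus juvenile results and the settings for scan day, slide 1, the detection covariate and single slides were chosen after the data had been seen. Among alternatives for single named genes, 3865 kept their direction and side of the threshold, 213 kept the direction without passing, 11 passed where the first fit had not, and 7 reversed. These counts pool each gene with each setting. Most are of genes that had not passed, for which the same side means still not passing. Of the 18 genes named for RA minus HVC, 16 lost their call with slide fixed and 7 with slide random. All 5 of HVC old minus juvenile lost theirs with slide fixed. The axon guidance result in RA kept its direction and its side of the threshold in all 34 alternatives run. Each was judged by the unadjusted p of camera at the preset correlation of 0.01. The estimated correlation was 0.227, and the alternatives were not run with it. They reuse the same arrays and do not lift the limit that the list was not higher on slides 6 and 8. Signal near background limits genes such as BARD1 and Olfr131. The cause of the changes below was not tested, except that fixed slide blocks use within-slide contrasts only and single-group fits use fewer arrays. The series table alternative was not run for RA or for RA minus HVC.

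In HVC, old minus young (8) gave 4 with the series table, 4 with slide as a fixed block, 8401 with array weights, 22 at an adjusted p of 0.1 and 5 with scan day as a block. Old minus juvenile (1280) gave 20 with slide fixed, 633 with slide random, 11782 with array weights, 3305 at 0.1 and 100 with scan day. Deafening in young birds gave 1 with slide random and 1 with array weights, deafening in old birds 5372 with array weights, the interaction 10 with array weights, the correlation of age changes 0.172 with array weights, and young minus juvenile in deafened birds 2 with only its groups.

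In RA, the mean deafening difference gave 1 with slide random, 1 with array weights and 1 at 0.1. Deafening in young birds gave 1 with quantile normalization, 1 with slide random, 19 with array weights and 1 at 0.1, and MTNR1A reversed to -0.0328 with array weights. Deafening in old birds gave 4 with slide fixed, 1 with slide random, 1 with age and slide pairs as a block and 2 with only its groups. Old minus young (4) gave 1 with slide fixed, 7 with all 36 arrays, 1 with only its groups, 0 with scan day and 0 without slide 1. Old minus juvenile (32) gave 2 with slide fixed, 51 with array weights, 78 at 0.1, 92 with all 36 arrays, 7 with only its groups, 18 with scan day and 1 without slide 1. Young minus juvenile gave 1 with array weights in intact birds and 2 with only its groups in deafened birds.

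RA minus HVC (7760) gave 253 with slide fixed, 3800 with slide random, 4006 with a 1.5-fold minimum and 3 on slide 9 only. Within deafened birds it gave 665 in juvenile, 289 in young and 121 in old birds, and within intact birds 439, 634 and 727. Direction reversed for the D1D-like receptor (0.36) and Abca6 (0.0440) in deafened old birds, ETV1 (-0.0598) in deafened young birds, the D3 receptor (-0.13) and NKX2-2 (-0.00597) in intact juveniles, and SLIT3 (-0.16) in intact young birds.

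With each array left out in turn, RA minus HVC ranged from 7025 to 8692. In HVC old minus young ranged from 7 to 92 (92 without deafened old array 1, 14 without deafened juvenile array 1), and old minus juvenile from 289 to 2917. The latter fell below 1280 by over 1.5 times without deafened juvenile arrays 2 (289) and 3 (566), intact juvenile arrays 1 (510), 2 (615) and 3 (839), deafened old array 3 (475) and intact old arrays 2 (846) and 3 (308). Young minus juvenile ranged from 0 to 1 in intact birds (1 without deafened young array 2) and from 0 to 1 in deafened birds (1 without deafened young array 3), and the HVC correlation from 0.145 to 0.406. All other HVC counts stayed at 0. In RA the mean deafening difference ranged from 0 to 1 (1 without deafened old array 2), deafening in juveniles from 0 to 1 (1 without juvenile array 3 of either state), and deafening in young birds from 0 to 3 (3 without intact juvenile array 3, 1 without deafened young array 4). Deafening in old birds stayed at 0. Young minus juvenile ranged from 0 to 1 (1 without intact juvenile array 3 or deafened young array 4), from 0 to 2 in intact birds (2 without intact juvenile array 3) and from 0 to 1 in deafened birds (1 without deafened juvenile array 3, deafened young array 4 or intact young array 2). The interaction ranged from 0 to 3 (3 without intact juvenile array 3), and the correlation from 0.018 to 0.165 (0.0713 without intact juvenile array 1). Old minus young ranged from 2 to 6, with 2 without any of 9 arrays: deafened old 1 and 3, deafened young 5, intact juvenile 1, 3 and 4, intact old 2, and intact young 4 and 5. Old minus juvenile ranged from 8 to 49, with 49 without deafened juvenile array 3, 8 without deafened juvenile array 1 or deafened old array 3, 9 without deafened juvenile 4, intact juvenile 4 or intact old 2, 11 without intact juvenile 3, 12 without intact juvenile 1, 14 without deafened old 1, 15 without deafened old 2 or intact old 3, and 18 without deafened young 5.

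Replicate numbers did not pair the samples throughout. Deviations of same-numbered intact and deafened samples of 1 age correlated from -0.118 to 0.437 in HVC, above 0.1 in 6 of 9 pairs, and from -0.262 to 0.519 in RA, above 0.1 in 7 of 9. The best partner had the same number for 5 of 9 in HVC and 6 of 9 in RA, and lay on the same slide for 8 of 9 in each area. Same-slide correlations were -0.024 to 0.437 in HVC and 0.106 to 0.519 in RA. Most same-numbered pairs also shared a slide, so number and slide cannot be told apart there. With the numbers as a block, deafening counts stayed at 0 in both areas, old minus young gave 1 and old minus juvenile 11 in RA, and no other count moved by over 1.5 times.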

Other observations

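The hypothesis that the change from juvenile to old birds is shared by both areas was formed after the results were seen, and so were the tests of old against juvenile birds below, the one on RA slide 8 and those of change left under a slide block after their values. Across 40070 probes the changes in HVC and RA correlated at r = 0.563 (rho = 0.513) on arrays off slide 9, which holds both areas, and at 0.623 over all arrays. Among 100 splits of the RA arrays by age, 1, the real one, gave a value as large, and the highest other was 0.488. All 31 probes called in RA and tested in both areas had the same sign in HVC, and 22 were called in both. These counts use all arrays, slide 9 included, and the share to be found without a common change was not computed. The pattern may reflect ageing common to both nuclei, but some birds gave both areas and the labels do not say which, so that differences between single birds remain open. The splits exchanged arrays across slides and scan days, over which ages were spread unevenly. Differences between slides or scan days therefore remain open too. A test of the difference between the areas' age changes called 0 of 40486 probes in limma, with 1334 at an unadjusted p under 0.05.

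Old minus juvenile in HVC was set against differences between slides, which could produce such calls because ages were spread unevenly over slides. Of the 500 probes with the smallest p on the other slides, 87.6% moved the same way on slide 7, which holds both ages. The other splits of its 4 arrays gave at most 69.0%. This argues against slides as the whole cause, though 4 arrays allow too few splits to exclude chance. Of 100 splits of the arrays only the real one reached 1280 calls, which excludes a chance assignment of single arrays, but the highest other, with 964, parted the arrays exactly by slide and scan day, and the blocked count was 20. Median changes of the 500 probes were 1.43 on the other slides and 0.53 on slide 7. Under the slide block the 1280 called changes kept a median of 73.2% of their size and a lowest of 21.1%. How much slides add to the size stays open. Signal quality as the whole cause is argued against by a count of 1620 with each array's share of detected probes as a covariate.

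RA minus HVC was also weighed against slides, since 8 of 9 slides hold 1 area. Of 6922 probes called without slide 9, 87.0% moved the same way on slide 9, against at most 74.2% for the other splits of its 4 arrays. That argues against slides as the whole cause, though 4 arrays allow too few splits to exclude chance. Median changes of these probes were 0.62 on the other slides and 0.51 on slide 9. The fixed slide block left 253 calls, but the called changes kept a median of 98.2% of their size, with a lowest of -199%, and their SE grew by a median of 2.88 times. Slide 9, on which the block rests, was among the arrays that picked these probes. The kept size is therefore no check apart from the one on slide 9. Slides as the source of single genes whose change shrank under the block, such as KCNA4 and EFNB2, remain open. Of 100 splits only the real one gave 7760 calls, with 18 as the highest other. These splits mixed arrays of different slides, so they exclude a chance assignment of single arrays and say nothing about slides. The detection covariate left 8389, which argues against signal quality as the whole cause. On slide 9 the arrays of both areas matched in age, at 787 days in intact and 783 days in deafened birds, and may come from the same birds. Age in days therefore cannot account for the agreement on slide 9. Different birds and dissection of each area remain untested, and so do ages in days on the other slides.

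Few deafening calls could arise if slide differences hid an effect. The main deafening tests held no slide term. With pairs of 1 age and slide as a block, 0 probes passed in the mean deafening difference of either area, so taking slides out brought no calls. How many real changes that fit would recover was not measured, so it cannot tell whether an effect was hidden. A small effect, or one in a few birds, remains open. For the mean deafening difference and the interaction the real count was 0, which all 100 splits reach by construction, so the splits say nothing about chance there. Their highest others were 11 and 5 in HVC and 3 and 5 in RA.

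Other splits gave these counts for the remaining comparisons. For young minus juvenile the real count was also 0, reached by all 100 splits by construction, and the highest others were 5 in HVC and 2 in RA. For old minus young 3 of 100 splits reached 8 calls in HVC, with 17 as the highest other, and 4 of 100 reached 4 calls in RA. Both shares lie under 0.05, but the splits exchanged arrays across slides, so they exclude chance only for arrays that are independent of slide. The highest RA split called 2545. It held all arrays of slides 1 and 8 on 1 side and all of slide 6 on the other, and it divided slides 2 and 9. A split that largely follows slides can thus call far more probes than the real one. Whether slides account for its count was not tested. The fixed slide block left 4 calls in HVC and 1 in RA, a scan day block left 5 and 0, and without slide 1 RA had 0. The called changes kept at least 74.4% of their size under the slide block in HVC and at least 103% in RA. These probes were picked on the same arrays, and the share asked was set after the values were known, so the sizes do not decide on slides. Across probes, the change on HVC slide 3, which held both ages, correlated at -0.00049 with that on the other slides. On RA slide 2 it correlated at -0.040. Differences between slides, scan days and single birds remain open. For old minus juvenile in RA 2 of 100 splits, exchanged in the same way, reached 32 calls; the highest other, 132, parted slides 1, 2 and 6 from slides 8 and 9, and with slide as a fixed block 2 calls were left. Of the 500 RA probes with the smallest p on the other slides, 79.8% moved the same way on slide 8, which holds both ages, against at most 69.0% for the other splits of its 4 arrays. That argues against slides as the whole cause, though 4 arrays allow too few splits to exclude chance. The 32 called changes kept at least 66.0% and a median of 93.4% of their size under the slide block. The lowest fell short of the share asked of every called change in the old minus young test, so these sizes do not decide on slides. Median changes of the 500 were 1.17 on the other slides and 0.38 on slide 8. Comparisons of 3 against 3 arrays allow 10 splits, too few for a share under 0.05, and all 10 reached the real 0. Their highest others in HVC were 0, 0 and 2 for deafening in juvenile, young and old birds and 0 for the age change in intact and in deafened birds. In RA they were 1, 0 and 8, then 2 and 4.

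Tests of whether a change differs between RA and HVC called 0 probes for deafening, young minus juvenile and old minus young as well, with 524, 985 and 1536 at an unadjusted p under 0.05 in limma.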
